A study of Rattus norvegicus with 16 samples.

How the data were processed

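Retinal RNA of newborn rats was measured on 16 single-colour Affymetrix gene arrays, hybridised with biotin-labelled sense-strand target prepared from total RNA without ribosomal RNA depletion, per the labels' protocols. The 8 groups of 2 arrays combine 2 strains, Fischer (F344) and Sprague Dawley (SD), with cyclic hyperoxia or room air and with post-natal day 5 or 6. Per the labels' protocols, the RNA of single rats was prepared first and then combined, so that each replicate is a pool. The series' design text speaks of 3 rats from 2 litters in connection with the pools, in wording that leaves open whether this is the make-up of each pool or of both together, and nothing in the labels ties a replicate number to a litter, a hybridisation batch or a scan date.

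The deposited table holds log2 expression values of 27342 probe sets on the 16 arrays, and per the submitters' processing notes these were made with Partek 6.4 and RMA. RMA corrects background, quantile-normalizes probe intensities across arrays and summarises the probes of a set on the log2 scale. No scanner files were analysed here, so background correction and normalization were taken as deposited, and a change common to most transcripts would have been removed by them. Array medians of the deposited values lay between 5.452 and 5.524 and interquartile ranges between 2.813 and 3.19. The number of arrays limits the precision.

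Probe sets were named through the platform annotation. Of the probe sets, 15097 had 1 gene symbol, 323 had several and 11922 were not listed. Of those with 1 symbol, 15067 were matched by Entrez identifier to the RefSeq gene table of the rat assembly GRCr8, which was used only for names, genomic span and the order of neighbouring genes, and 30 kept the annotated symbol. For the 499 genes with over 1 probe set, the set with the highest mean over all arrays was taken, which left 14324 genes. Probe sets with several symbols or none entered only an alternative in which every probe set was tested on its own. No array was left out.

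Genes were tested with limma 3.58.1 in R 4.3.3. One mean per group was fitted to all 16 arrays, so that all groups share 1 estimate of the spread, with 8 residual degrees of freedom and 7.41 prior degrees of freedom from the empirical Bayes step. The 12 contrasts were the oxygen effect (cyclic hyperoxia minus room air) in each strain on each day, its mean over both strains on each day, its difference between strains (SD minus F344) on each day and between days (day 6 minus day 5) in each strain, and, among room air arrays, the strain difference (SD minus F344 over both days) and the day difference (day 6 minus day 5 over both strains). P values were adjusted with the Benjamini-Hochberg method over all genes of a contrast, and a gene was called at an adjusted p under 0.05. Errors given as ± after a log2 change are moderated standard errors with n = 2 arrays per group, and errors given as ± after a group value are SDs. Linear folds are ratios of geometric means.

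30 gene lists were fixed, of which 29 had at least 5 measured members and were tested with camera, limma's competitive gene set test, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists within a contrast. They cover hypoxia-responsive genes (targets of the hypoxia-inducible factors, HIF, outside glycolysis), glycolysis, angiogenic ligands and receptors, endothelial markers, endothelial tip cells, pericytes and smooth muscle, astrocytes, Muller glia, glial stress, rods, cones, bipolar cells, amacrine and horizontal cells, ganglion cells, the cell cycle, retinal progenitors, microglia and macrophages, erythroid cells, lens, pigment epithelium with choroid and ciliary body, skeletal muscle, antioxidant and NRF2 targets, interferon and antigen presentation, p53 targets, cholesterol synthesis, immediate early genes, ATF4 and endoplasmic reticulum stress, the circadian clock, and basement membrane and matrix. The last list, sex-linked genes, had 0 measured members and could not be tested. Camera with an estimated correlation, fry and camera on ranks were the other set tests.

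The genes named in the text follow a fixed rule. For each oxygen effect they are the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups, the 4 members with the smallest p of each called list, and always Vegfa, Epo, Igf1, Adm, Angpt2, Slc2a1, Gfap and Edn2. For the differences between strains or days and for the room air contrasts they are the 8 largest called genes each way, or the 4 with the smallest p each way where fewer than 4 passed. Further members of the lists, and genes called in both of a pair of comparisons, are named as examples chosen after their values were seen. Globins, RT1 genes, olfactory receptors and other families of near-identical copies are uncertain, because their probes can share targets. The samples, contrasts, tests, gene lists, rule for named genes and the alternatives listed first below were fixed before the data were examined.

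The calculation was tested on simulated data with the real genes' means and spreads. Over 14324 simulated genes with 50 genes changed at each size, the simulated oxygen effect in SD at day 5 recovered 42% of changes of 0.5 on the log2 scale, 92% of changes of 1, 98% of changes of 1.5 and 100% of changes of 2, with 10 false calls among 176. The mean effect over both strains at day 5 recovered 78%, 92%, 100% and 100%, with 6 false calls among 191, and the strain difference at day 6 recovered 6%, 62%, 92% and 100%, with 1 false call among 131. In the list test for the oxygen effect in SD at day 5, both of 2 lists moved by −0.3 were called and 0 lists without a moved gene. The simulated genes varied independently of each other, so this does not test the list calls where the members of a list are correlated.

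The alternatives tried were quantile normalization of the deposited values, median centring, omission of the 4775 genes with the lowest means, the mean of a gene's probe sets, every probe set on its own, a fold of at least 1.5 as well, moderation with a trend and robust fitting, no moderation, array weights, fits on the compared groups alone, a replicate block within each day, and omission of each array in turn, where an arm left with 1 array is assumed to vary like the other groups. Chosen after seeing the data were a covariate for each array's interquartile range, gene lists recomputed without replicate 2 of the F344 hyperoxia group of day 6, and gene families defined by symbol.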

Results

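Gene expression was measured in the retina of newborn rats of an oxygen-induced retinopathy model, in which blood vessel growth in the immature retina is disturbed by changing oxygen levels. The study set a susceptible strain against a resistant one. Sprague Dawley (SD) rats are generally known as susceptible and Fischer (F344) rats as resistant. Starting within 12 h of birth, treated rats breathed 80% and 21% oxygen in turns of 24 h, and controls stayed in room air. Retinae were taken on post-natal day 5 and day 6, which gave 8 groups of 2 arrays each, every array holding a pool of RNA. The labels do not state which oxygen level preceded each day. Counted from hyperoxia as the first phase, day 5 would fall at the end of a hyperoxic day and day 6 at the end of a day at 21% oxygen. The comparisons ask how cyclic hyperoxia changes retinal expression on each day and whether the strains differ. P values measure only the spread between these pools, and the number of arrays limits the precision.

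Arrays of the same group correlated with Pearson's r between 0.987 and 0.997 across genes, which are not independent replicates. Replicate 2 of the F344 hyperoxia group of day 6 stood apart from the other arrays. Its interquartile range of 2.81 was the lowest and its median of 5.52 the highest, and its r with its partner, 0.987, was the lowest of the 8 pairs. In that pair 70 genes differed over 2-fold, against 0 to 34 in the other groups. Array values include background. Folds against a group mean under 5.45, the lowest median of an array, are therefore given as lower bounds. Log2 changes of such genes, among them Egln3 on day 5, Tek, Slc38a5, Tap2, Ly6g6d, Gng11, Col5a3, Pax4 and Pth2r, are to be read the same way.

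On day 5, hyperoxia lowered a set of oxygen-regulated genes in SD retina. Slc16a3, a lactate exporter (probe set 10740209), was 2.98-fold lower than in room air (log2 change −1.57 ± 0.23 SE, n = 2 arrays per group, adjusted p = 0.0115), at 6.04 ± 0.23 against 7.61 ± 0.38 (SD). Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor (HIF) for degradation (10889923), was at least 2.29-fold lower (adjusted p = 0.00386). Ak4, a mitochondrial adenylate kinase (10870261), was 2.17-fold lower (adjusted p = 0.00501). Vegfa, the main angiogenic growth factor of the retina (10921772), was 2.01-fold lower (−1.01 ± 0.13, adjusted p = 0.00501), at 8.07 ± 0.2 against 9.07 ± 0.09. Also lower were Pdk1, a kinase that restrains pyruvate oxidation (−0.97 ± 0.11, adjusted p = 0.00371), and the glycolytic regulator Pfkfb3 (−0.92, adjusted p = 0.0148). So were the mitophagy gene Bnip3 (−0.82, adjusted p = 0.0148), the endothelial receptor Adgrl4 (−0.75, adjusted p = 0.0365) and the glycolytic enzyme Gpi (−0.70, adjusted p = 0.0229). These 9 were all the genes called among 14324, and 0 were higher. In all, 1296 genes had an unadjusted p under 0.05. The count was 15 without either array of the F344 hyperoxia group of day 6 and 4 without SD hyperoxia day 5 replicate 2. It was 0 without SD hyperoxia day 5 replicate 1 or SD room air day 5 replicate 1 (432 and 1322 genes at an unadjusted p under 0.05). Thus 0 of the 9 genes were called in all 16 fits with an array left out.

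In F344 retina on day 5, many of the same genes were lower. Egln3 fell at least 2.57-fold (−1.36 ± 0.15, n = 2 arrays per group, adjusted p = 0.00133), from 6.11 ± 0.28 to 4.75 ± 0.01, and Slc16a3 fell 2.68-fold (−1.42 ± 0.23, adjusted p = 0.021). Ak4 (−1.25, adjusted p = 0.00163), Pfkfb3 (−1.23, adjusted p = 0.00133), the collagen prolyl hydroxylase P4ha1 (−1.10, adjusted p = 0.0217), and the HIF target Ankrd37 (−0.99, adjusted p = 0.0134) fell too. Bnip3 (−0.91, adjusted p = 0.00765) and the glycolytic enzyme Pgk1 (−0.85, adjusted p = 0.0217) were lower. Vegfa fell 1.77-fold (−0.83 ± 0.13, adjusted p = 0.021). Among vascular genes, the angiopoietin receptor Tek (−0.88 ± 0.15, adjusted p = 0.0328), Adgrl4 (−0.76, adjusted p = 0.0217) and the transcription factor Ets1 (−0.73, adjusted p = 0.0431) fell. The globins Hbb-b1 (−1.36, adjusted p = 0.0168) and Hbb (−1.19, adjusted p = 0.0152) were called lower as well, but are near-identical copies and uncertain. In all, 18 genes were called, 0 of them higher. An unadjusted p under 0.05 was reached by 1198. The count was 4 without either array of the F344 hyperoxia group of day 5, 11 and 10 without replicates 1 and 2 of its room air group, and 10 without either array of the SD hyperoxia group of day 6. Egln3, Ak4 and Pfkfb3 were the 3 of 14 named genes called in all 16 fits with an array left out.

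The strains shared 8 of these falls (Adgrl4, Ak4, Bnip3, Egln3, Pdk1, Pfkfb3, Slc16a3 and Vegfa), against 0.0113 if their calls were independent, which the shared spread does not allow. Averaged over both strains on day 5, 30 genes fell and 0 rose, with 1607 at an unadjusted p under 0.05. Slc16a3 fell 2.83-fold (−1.50 ± 0.16, n = 2 arrays per group, adjusted p = 0.000196). Egln3 fell at least 2.43-fold (−1.28 ± 0.10, adjusted p = 2.97e-05) and Vegfa 1.89-fold (−0.92 ± 0.09, adjusted p = 0.00013). Further falls were seen in Ak4 (−1.18, adjusted p = 4.31e-05), Pfkfb3 (−1.07, adjusted p = 4.31e-05) and Pdk1 (−0.86, adjusted p = 4.31e-05). Others were in hexokinase Hk2 (−1.40 ± 0.27, adjusted p = 0.0452) and P4ha1 (2.01-fold, adjusted p = 0.00142). Slco1c1, a thyroid hormone transporter of brain vessels (−1.07, adjusted p = 0.00949), fell as well. Igfbp2, which binds insulin-like growth factors, did so too (−0.92, adjusted p = 0.00142). The glucose transporter Slc2a1 (−0.33, adjusted p = 0.409), Epo (0.21, adjusted p = 0.402), and Igf1 (−0.27, adjusted p = 0.3) did not pass. Neither did Adm (−0.17, adjusted p = 0.528), Angpt2 (0.10, adjusted p = 0.761), Gfap (0.17, adjusted p = 0.602) and Edn2 (0.10, adjusted p = 0.659). The count of 30 was 16 and 14 without F344 hyperoxia day 5 replicates 1 and 2 and 54 without either array of the F344 hyperoxia group of day 6. It was 15 without either array of the SD hyperoxia group of day 5 and 17 without SD room air day 5 replicate 1. Of 18 named genes, 12 were called in all 16 fits with an array left out, among them Slc16a3, Egln3, Ak4, Vegfa, Tek and Adgrl4. Hk2, Slco1c1, Pfkp, Flt1, Adgrf5 and Ets1 were not called without either F344 hyperoxia array of day 5 or without SD hyperoxia day 5 replicate 1.

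As a group, 9 of 29 hypoxia-responsive genes fell over both strains on day 5 (15 adjusted over the list alone), with a mean log2 change of −0.41 (camera adjusted p = 4.47e-24; adjusted p = 0.00274 with an estimated correlation). In SD the list fell with 5 called members (14 adjusted over the list alone, mean −0.39, camera adjusted p = 6.5e-16; adjusted p = 0.0114 with an estimated correlation). In F344 it fell with 7 (13 adjusted over the list alone, mean −0.44, camera adjusted p = 1.07e-19; adjusted p = 0.00554 with an estimated correlation). Of 20 glycolysis genes, 7 fell over both strains (13 adjusted over the list alone, mean −0.48, camera adjusted p = 8.9e-21; adjusted p = 0.0689 with an estimated correlation). Examples were Gpi (−0.60, adjusted p = 0.00142) and the phosphofructokinase Pfkp (−0.73, adjusted p = 0.0112). The glycolysis list was also called in SD (3 members, 8 adjusted over the list alone, mean −0.46, camera adjusted p = 3.31e-13; adjusted p = 0.21 with an estimated correlation). F344 gave the same direction (3 members, 9 adjusted over the list alone, mean −0.50, camera adjusted p = 2.2e-16; adjusted p = 0.0989 with an estimated correlation). These calls held without any 1 array.

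Vascular lists fell on day 5 as well. Of 29 endothelial markers, 5 fell over both strains (10 adjusted over the list alone, mean −0.24, camera adjusted p = 2.7e-11; adjusted p = 0.0677 with an estimated correlation). They were Tek (−0.79 ± 0.11, adjusted p = 0.00235), Adgrl4 (−0.75, adjusted p = 0.000526), Adgrf5 (−0.84, adjusted p = 0.0131), Flt1 (−0.45, adjusted p = 0.0194) and Slc38a5 (−0.71, adjusted p = 0.0441). In SD it was called with few members (1 called, 8 adjusted over the list alone, mean −0.22, camera adjusted p = 1.75e-06; adjusted p = 0.21 with an estimated correlation). In F344 it was called too (2 members, 6 adjusted over the list alone, mean −0.25, camera adjusted p = 2.2e-09; adjusted p = 0.0831 with an estimated correlation). Of 33 angiogenic ligands and receptors, 3 fell over both strains (7 adjusted over the list alone, mean −0.17, camera adjusted p = 2.86e-07; adjusted p = 0.0222 with an estimated correlation). These were Vegfa, Tek and the VEGF receptor Flt1. In SD that list had 1 called member (4 adjusted over the list alone, mean −0.17, camera adjusted p = 7.02e-05; adjusted p = 0.0818 with an estimated correlation). In F344 it had 2 (5 adjusted over the list alone, mean −0.17, camera adjusted p = 4.07e-05; adjusted p = 0.0669 with an estimated correlation). These calls also held without any 1 array, though the endothelial mean in F344 was −0.14 without F344 room air day 5 replicate 2. Pericyte and smooth muscle genes, 14 measured, were lower as a list over both strains (0 called, 4 adjusted over the list alone, mean −0.21, camera adjusted p = 0.000522; adjusted p = 0.109 with an estimated correlation). The same held in SD (0 and 0, mean −0.19, camera adjusted p = 0.0123; adjusted p = 0.334 with an estimated correlation), where the call was lost without SD room air day 5 replicate 1. It held in F344 (0 and 2, mean −0.22, camera adjusted p = 0.00677; adjusted p = 0.194 with an estimated correlation), where it was lost without F344 room air day 5 replicate 2. The pericyte gene Rgs5 itself, at −1.28, did not pass (adjusted p = 0.0658).

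**Figure D1:**
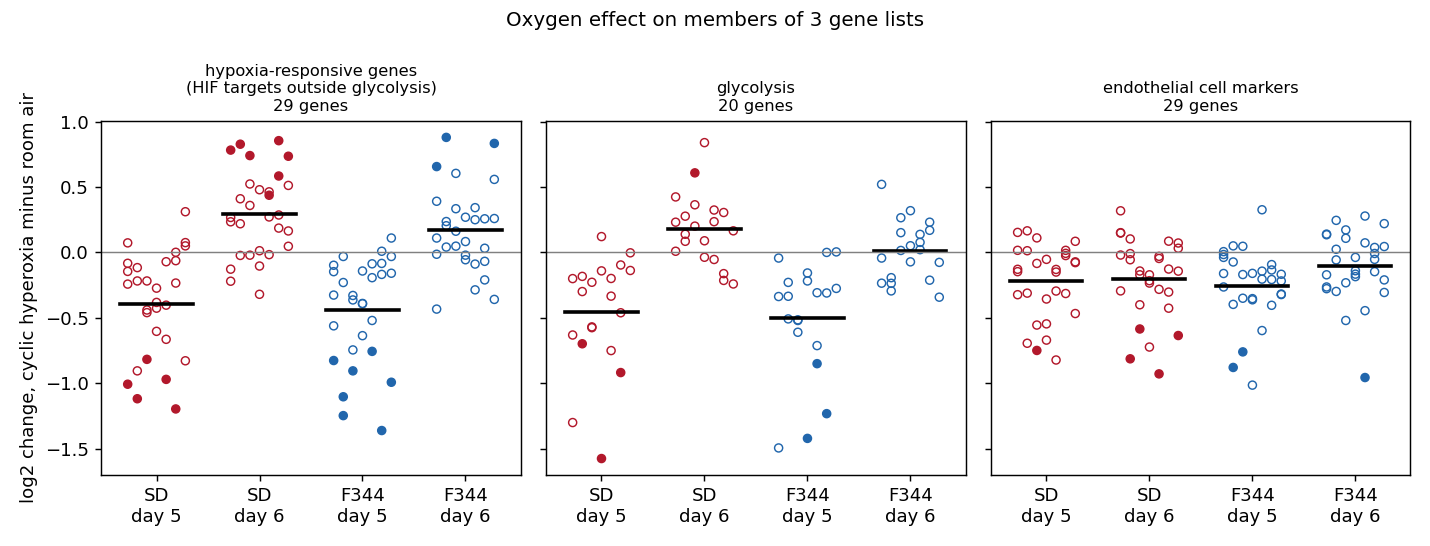
Log2 change with cyclic hyperoxia against room air (y axis) for each measured gene of the hypoxia-responsive, glycolysis and endothelial lists in each strain and day (x axis), with filled points for genes at an adjusted p under 0.05 and bars for list means. On day 5 the means lie between −0.50 and −0.22 in both strains, and on day 6 the hypoxia-responsive mean lies at 0.29 in SD and 0.17 in F344.

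Smaller list shifts on day 5 rested more on single arrays. Basement membrane and matrix genes, 21 measured, were lower over both strains (0 called, 2 adjusted over the list alone, mean −0.14, camera adjusted p = 0.000522; adjusted p = 0.239 with an estimated correlation). They were lower in SD (mean −0.14, camera adjusted p = 0.00993; adjusted p = 0.442 with an estimated correlation), lost without SD room air day 5 replicate 1. In F344 they were lower as well (mean −0.14, camera adjusted p = 0.00982; adjusted p = 0.494 with an estimated correlation), lost without F344 room air day 5 replicate 2. The 14 tip cell genes were lower in F344 (1 called, 2 adjusted over the list alone, mean −0.18, camera adjusted p = 0.00448; adjusted p = 0.07 with an estimated correlation). Over both strains they were lower too (1 and 1, mean −0.10, camera adjusted p = 0.0322; adjusted p = 0.131 with an estimated correlation). That call was lost without F344 hyperoxia day 5 replicate 1, F344 room air day 5 replicate 2, SD hyperoxia day 5 replicate 2 or SD room air day 5 replicate 2. In SD, cholesterol synthesis genes, 18 measured, were higher (0 called, mean 0.14, camera adjusted p = 0.0188; adjusted p = 0.509 with an estimated correlation), lost without replicate 2 of either SD group of day 5. They were higher over both strains (mean 0.11, camera adjusted p = 0.0183; adjusted p = 0.585 with an estimated correlation), lost without SD room air day 5 replicate 2. ATF4 and endoplasmic reticulum stress genes, 25 measured, were higher in SD (0 called, mean 0.14, camera adjusted p = 0.00993; adjusted p = 0.413 with an estimated correlation; lost without SD room air day 5 replicate 2). The 12 bipolar cell genes were lower in SD (0 called, mean −0.21, camera adjusted p = 0.0447; adjusted p = 0.509 with an estimated correlation). That call was lost without SD room air day 5 replicate 2 or any array of the SD hyperoxia or F344 room air groups of day 5.

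The cell cycle and rod lists moved differently in the strains on day 5. In SD the 34 cell cycle genes were higher as a list (0 called, 11 adjusted over the list alone, mean 0.37, camera adjusted p = 4.95e-12; adjusted p = 0.413 with an estimated correlation). Their mean was 0.11 without SD room air day 5 replicate 2 and 0.64 without its partner. The 21 rod genes were lower in SD (0 called, 1 adjusted over the list alone, mean −0.15, camera adjusted p = 0.0136; adjusted p = 0.549 with an estimated correlation). The call was lost at −0.13 without SD hyperoxia day 5 replicate 2 and at −0.07 without SD room air day 5 replicate 2, and the mean was −0.23 without the latter's partner. They were higher in F344 (0 and 0, mean 0.15, camera adjusted p = 0.00982; adjusted p = 0.672 with an estimated correlation). That call was lost at 0.06 without F344 hyperoxia day 5 replicate 1 and at 0.13 without F344 room air day 5 replicate 1, and the mean was 0.24 without F344 hyperoxia day 5 replicate 2. The difference between strains was called for rods (mean −0.30, camera adjusted p = 5.54e-05; adjusted p = 0.874 with an estimated correlation). It was also called for the cell cycle (mean 0.38, camera adjusted p = 7.48e-07; adjusted p = 0.91 with an estimated correlation). This call was lost at 0.20 without F344 hyperoxia day 5 replicate 1 and at 0.11 without SD room air day 5 replicate 2, and the mean was 0.65 without its partner. Over both strains the cell cycle mean was 0.18 (0 called, 3 adjusted over the list alone, camera adjusted p = 3.06e-06; adjusted p = 0.585 with an estimated correlation). It was 0.32 without SD room air day 5 replicate 1, 0.09 without F344 hyperoxia day 5 replicate 2, and 0.05 with the call lost without SD room air day 5 replicate 2. The 13 clock genes were lower in SD (0 called, mean −0.18, camera adjusted p = 0.00335; adjusted p = 0.509 with an estimated correlation). Over both strains they were lower too (mean −0.10, camera adjusted p = 0.0303; adjusted p = 0.624 with an estimated correlation), a call lost without F344 hyperoxia day 5 replicate 2, F344 room air day 5 replicate 1, SD hyperoxia day 5 replicate 1 or SD room air day 5 replicate 2.

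No gene passed the test for a strain difference of the oxygen effect on day 5, SD minus F344. By limma 0 genes were called, the smallest adjusted p was 0.641, and 879 genes had an unadjusted p under 0.05. The lowest p values belonged to Hbb-b1 (1.57) and Hbb (1.37), both at an adjusted p of 0.641 and uncertain as near-identical copies. Hbb lay at 6.32 and 7.51 in F344 hyperoxia and room air and at 7.1 and 6.92 in SD. Next came the uncertain olfactory receptor Or5h17 (0.87) and the chaperone Fkbp14 (0.74, adjusted p = 0.788). In the other direction came Irf2bpl (−1.05), Prelid1 (−0.76), Grik3 (−0.77) and Gng7 (−0.64), each at an adjusted p of 0.788. As a list, the oxygen effect on the 13 erythroid genes was more positive in SD than in F344 (0 called, 2 adjusted over the list alone, mean difference 0.30, camera adjusted p = 0.0217; adjusted p = 0.874 with an estimated correlation). This was lost without F344 hyperoxia day 5 replicate 1, F344 room air day 5 replicate 2, SD hyperoxia day 5 replicate 1 or SD room air day 5 replicate 1. Without F344 room air day 5 replicate 1, 2 genes were called.

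On day 6 in SD retina, 319 genes were called higher and 81 lower after hyperoxia. The largest rises were in Cox4i2, an oxygen-responsive subunit of cytochrome c oxidase (10840895; 2.62-fold, 1.39 ± 0.23, n = 2 arrays per group, adjusted p = 0.0123), and the glutathione transferase Gstm5 (2.52-fold, 1.33 ± 0.19, adjusted p = 0.00758). Next came the histone gene H2ac21 (1.27, adjusted p = 0.0303), the RNA polymerase II subunit Polr2d (1.19, adjusted p = 0.00568) and the ferritin chain Fth1 (1.13, adjusted p = 0.0247). Cox4i1 (1.08, adjusted p = 0.0231), Fam136a (1.06, adjusted p = 0.00758) and the incretin receptor Gipr (1.05, adjusted p = 0.0141) followed. Egln3, lower on day 5, was 1.81-fold higher (0.85 ± 0.15, adjusted p = 0.0125). Adm, which encodes the vasodilator adrenomedullin (10709875), was at least 1.77-fold higher (0.83 ± 0.14, adjusted p = 0.0123), at 5.73 ± 0.14 against 4.9 ± 0.05. The metal-binding Mt1 rose 1.76-fold (0.82 ± 0.13, adjusted p = 0.0123). Fam162a (0.78, adjusted p = 0.0171) and Higd1a (0.74, adjusted p = 0.0125), both HIF targets of mitochondria, rose too. Among falls were the synaptic genes Cntnap4 (−0.95, adjusted p = 0.0123) and Unc13c (−0.93, adjusted p = 0.0288) and the amino acid transporter Slc38a5 (−0.93 ± 0.19, adjusted p = 0.021). Lrp1b (−0.83, adjusted p = 0.047), Prkca (−0.81, adjusted p = 0.0235), the efflux pump Abcc1 (−0.80, adjusted p = 0.00857) and Bmp15 (−0.77, adjusted p = 0.0123) fell too. The endothelial Tek fell (−0.81 ± 0.15, adjusted p = 0.0151). Vegfa (0.23 ± 0.13, adjusted p = 0.372), Slc2a1 (0.48, adjusted p = 0.223), Igf1 (−0.33, adjusted p = 0.17), Epo (0.16), Angpt2 (0.21), Gfap (0.31) and Edn2 (−0.09) did not pass.

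The 400 calls in SD on day 6 stood beside 2692 genes at an unadjusted p under 0.05. Without SD hyperoxia day 6 replicate 1 or 2 or SD room air day 6 replicate 1 the count was 0, with 1337, 2299 and 1873 genes at an unadjusted p under 0.05. It was 221 without SD room air day 6 replicate 2, 994 without either array of the F344 hyperoxia group of day 6 and 260 without either array of its room air group. None of the 25 named genes was therefore called in all 16 fits (0 of 25). Of the 29 hypoxia-responsive genes, 7 rose (11 adjusted over the list alone, mean 0.29, camera adjusted p = 5.74e-06; adjusted p = 0.212 with an estimated correlation). Of 29 endothelial markers, 4 fell (6 adjusted over the list alone, mean −0.20, camera adjusted p = 0.00435; adjusted p = 0.724 with an estimated correlation), lost without SD room air day 6 replicate 2. Emcn lay at −0.64 (adjusted p = 0.0235) and Adgrl4 at −0.58 (adjusted p = 0.0233) beside Tek. Of 30 antioxidant genes, 5 rose (8 adjusted over the list alone, mean 0.18, camera adjusted p = 0.0465; adjusted p = 0.516 with an estimated correlation). Among them were Gsta4 (1.01, adjusted p = 0.0276) and the peroxiredoxin Prdx1 (0.68, adjusted p = 0.0303). The call was lost without any SD array of day 5, either array of the F344 hyperoxia group of day 6, SD hyperoxia day 6 replicate 2 or SD room air day 6 replicate 2.

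In F344 on day 6, 49 genes rose and 121 fell. The largest rise was in Ndufb3, a subunit of respiratory complex I (10923576; 2.22-fold, 1.15 ± 0.15, n = 2 arrays per group, adjusted p = 0.0105). It was followed by the transcriptional inhibitor Id3 (1.14, adjusted p = 0.0396) and by Ak4 (1.84-fold, 0.88 ± 0.15, adjusted p = 0.0191). Next came calmodulin Calm2 (0.84, adjusted p = 0.0326), Ift25 (0.84, adjusted p = 0.0191) and Higd1a (0.83 ± 0.13, adjusted p = 0.0191). Snrpg (0.82, adjusted p = 0.0467) and Cwc15 (0.81, adjusted p = 0.023), both of the splicing machinery, rose too. The cell cycle kinase Cdk4 fell most (10895797, 1.98-fold, −0.99 ± 0.15, adjusted p = 0.0191), ahead of Kcne5 (−0.97, adjusted p = 0.023) and Slc38a5 (−0.96 ± 0.19, adjusted p = 0.0328). So did the mitochondrial carrier Ucp2 (−0.92, adjusted p = 0.0191), Trib1 (−0.91, adjusted p = 0.0191) and Pmepa1 (−0.91, adjusted p = 0.0297). Cnpy3 (−0.87, adjusted p = 0.0191) and Mrpl38 (−0.84, adjusted p = 0.0286) were next. Of 29 hypoxia-responsive genes, 3 rose (5 up and 1 down adjusted over the list alone, mean 0.17, camera adjusted p = 0.00452; adjusted p = 0.715 with an estimated correlation). Fam162a was among them (0.66, adjusted p = 0.0491). Ankrd37 (0.56, adjusted p = 0.0681), Vegfa (0.11, adjusted p = 0.711) and Adm (0.20, adjusted p = 0.47) did not pass. The 13 clock genes fell as a list (1 called, 9 adjusted over the list alone, mean −0.37, camera adjusted p = 6.35e-06; adjusted p = 0.715 with an estimated correlation). The repressor Nr1d1 was called (−0.73, adjusted p = 0.0388). Per3 (−0.56, adjusted p = 0.0561), Per1 (−0.45, adjusted p = 0.0626) and Nfil3 (−0.61, adjusted p = 0.0684) were not. Retinal progenitor genes, 16 measured, were lower (0 called, 0 adjusted over the list alone, mean −0.22, camera adjusted p = 0.0318; adjusted p = 0.821 with an estimated correlation).

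The 170 calls in F344 on day 6, beside 2522 genes at an unadjusted p under 0.05, involve the array that stood apart. Without it the count was 0 (1933 genes at an unadjusted p under 0.05). With it as the lone hyperoxia array, without replicate 1, the count was 1621. It was also 0 without F344 room air day 6 replicate 1 or 2 (1607 and 1603 genes at an unadjusted p under 0.05). It was 31 without either array of the SD hyperoxia group of day 5 and 61 without either of that of day 6. Of the named genes, 0 of 18 were called in all 16 fits. Without the array that stood apart, a recalculation chosen after seeing the data, the hypoxia-responsive mean was 0.23 (camera adjusted p = 0.000272; adjusted p = 0.283 with an estimated correlation). The clock mean was then −0.27 (camera adjusted p = 0.000531; adjusted p = 0.534 with an estimated correlation). Rod genes (mean 0.31, camera adjusted p = 0.000152; adjusted p = 0.43 with an estimated correlation) and lens genes (mean −0.53, camera adjusted p = 0.00255; adjusted p = 0.534 with an estimated correlation) were called by the preset correlation alone. Without replicate 1, the hypoxia-responsive mean was 0.11 and its call and that of the progenitor genes were lost.

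Averaged over both strains on day 6, 575 genes rose and 391 fell, with 3425 at an unadjusted p under 0.05. Gstm5 rose 1.88-fold (0.91 ± 0.13, n = 2 arrays per group, adjusted p = 0.00325) and Higd1a 1.72-fold (0.78 ± 0.09, adjusted p = 0.00216). Gsta4 (0.92, adjusted p = 0.00728), Fam162a (0.72, adjusted p = 0.00325), and Ak4 (0.65, adjusted p = 0.00514) rose too. So did Mt1 (0.64 ± 0.09, adjusted p = 0.00325), Egln3 (0.56, adjusted p = 0.00899) and Adm (0.52, adjusted p = 0.0102). Larger rises were seen in Ccdc107 (1.21, adjusted p = 0.0218), H2ac21 (adjusted p = 0.0134) and Fth1 (0.94, adjusted p = 0.00899). Others were in Mrps34 (0.88, adjusted p = 0.02), Cox4i2 (0.87, adjusted p = 0.00972) and the proteasome component Sem1 (0.87, adjusted p = 0.0227). These 6 lost their call without SD hyperoxia day 6 replicate 1, and 4 of them (Ccdc107, H2ac21, Mrps34 and Sem1) also without F344 room air day 6 replicate 1 or 2. Slc38a5 fell (−0.94 ± 0.14, adjusted p = 0.00325). Vac14 (−0.61, adjusted p = 0.00325) and the potassium channel Kcna3 (−0.59, adjusted p = 0.0062) fell too. The other large falls were in Tex26 (−0.61), Sarm1 (−0.61), Cuedc1 (−0.60), Tp53inp1 (−0.59) and Slc6a11 (−0.58), all lost without SD hyperoxia day 6 replicate 1. Vegfa stayed under the threshold (0.17, adjusted p = 0.284). The strains shared 18 calls in the same direction, such as Higd1a, Fam162a, Calm2, Cox7b, Slc38a5 and Vac14, against 1.78 if their calls were independent. They shared 1, Plbd2, in opposite directions.

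Of the 29 hypoxia-responsive genes, 10 rose over both strains on day 6 (13 up and 1 down adjusted over the list alone, mean 0.23, camera adjusted p = 4.44e-06; adjusted p = 0.202 with an estimated correlation). Of 29 endothelial markers, 5 fell (6 adjusted over the list alone, mean −0.15, camera adjusted p = 0.0168; adjusted p = 0.704 with an estimated correlation). Among them were Tek (−0.55 ± 0.11, adjusted p = 0.0107), Tie1 (−0.46, adjusted p = 0.0125) and Emcn (−0.47, adjusted p = 0.0131). The call was lost without F344 hyperoxia day 6 replicate 1 or SD room air day 6 replicate 2. Of 13 clock genes, 3 fell (5 adjusted over the list alone, mean −0.21, camera adjusted p = 0.00209; adjusted p = 0.704 with an estimated correlation). These were Per3 (−0.39, adjusted p = 0.028), Npas2 (−0.29, adjusted p = 0.04) and Clock (−0.40, adjusted p = 0.0424). Like the 3 endothelial genes, they lost their calls without SD hyperoxia day 6 replicate 1. Of 30 antioxidant genes, 6 rose and 1 fell (9 and 2 adjusted over the list alone, mean 0.13, camera adjusted p = 0.0499; adjusted p = 0.597 with an estimated correlation). The antioxidant call ended in 8 of the 16 fits with an array left out, those without any SD array of day 5, F344 hyperoxia day 6 replicate 1, F344 room air day 6 replicate 2, SD hyperoxia day 6 replicate 2 or SD room air day 6 replicate 2. The count of 966 genes was 2829 and 491 without F344 hyperoxia day 6 replicates 1 and 2. It was 218 and 192 without F344 room air day 6 replicates 1 and 2, and 53 without SD hyperoxia day 6 replicate 1. It was 463 without SD room air day 6 replicate 1. Of the named genes, 11 of 29 were called in all 16 fits, among them Gstm5, Gsta4, Higd1a, Fam162a, Ak4, Egln3, Mt1, Adm and Slc38a5.

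The oxygen effect differed between strains on day 6 for 8 genes. It was more positive in SD for Slc35a4 (difference of log2 changes, SD minus F344, 1.33 ± 0.20, n = 2 arrays per group, adjusted p = 0.0192), and Fibp (1.29 ± 0.18, adjusted p = 0.018). For Plbd2 it was 0.62 in SD and −0.59 in F344 (1.21 ± 0.17, adjusted p = 0.018). Others were the GTPases Rnd2 (1.09, adjusted p = 0.0192) and Rhob (0.92, adjusted p = 0.033), Pkdcc (0.98, adjusted p = 0.0192) and Dpysl4 (0.92, adjusted p = 0.033). It was more negative in SD for the muscarinic receptor Chrm2 (−0.92 ± 0.15, adjusted p = 0.033). The clock list differed by a mean of 0.32 (0 genes called, 2 adjusted over the list alone, camera adjusted p = 0.00621; adjusted p = 0.815 with an estimated correlation). This was lost without replicate 2 of the SD or of the F344 hyperoxia group of day 6. Beside the 8 genes, 1641 had an unadjusted p under 0.05. The count was 181 and 24 without F344 hyperoxia day 6 replicates 1 and 2, 5 without any array of the F344 hyperoxia, F344 room air or SD hyperoxia groups of day 5. It was 0 without F344 room air day 6 replicate 1 or 2, SD hyperoxia day 6 replicate 1 or 2, or SD room air day 6 replicate 1 (1199, 1315, 1294, 1305 and 1441 genes at an unadjusted p under 0.05). Thus 0 of the 8 were called in all 16 fits.

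**Figure D2:**
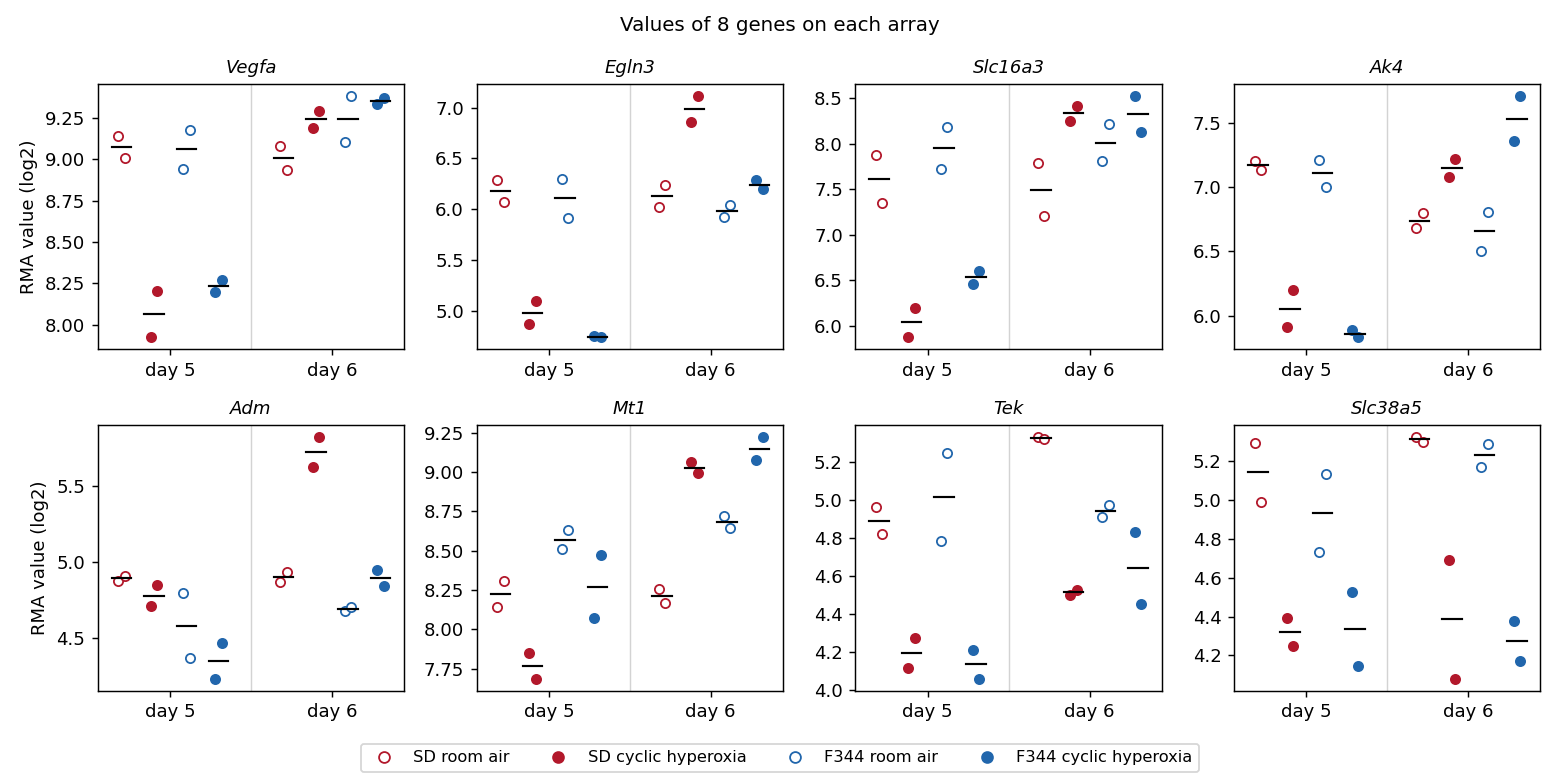
RMA log2 values per array (y axis) of 8 genes on day 5 and day 6 (x axis), SD in red and F344 in blue, with open points for room air, filled points for cyclic hyperoxia and bars for group means. Vegfa lies at 8.07 in SD and 8.23 in F344 after hyperoxia on day 5 and at 9.24 and 9.35 on day 6.

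The oxygen effect was more positive on day 6 than on day 5 for oxygen-regulated genes in both strains. In SD 16 genes differed, 16 of them more positive on day 6 and 0 more negative. They were led by Slc16a3 (difference of log2 changes 2.41 ± 0.32, n = 2 arrays per group, 5.33-fold, adjusted p = 0.00586), Cox4i2 (2.13, adjusted p = 0.0119) and Egln3 (2.05 ± 0.21, at least 4.14-fold, adjusted p = 0.000623). Igfbp2 (1.78, adjusted p = 0.00586), Gipr (1.64, adjusted p = 0.0182) and Ak4 (1.53, adjusted p = 0.00586) followed. Then came the glycogen phosphorylase Pygl (1.49, adjusted p = 0.00781) and Pdk1 (1.41, adjusted p = 0.00134). Hypoxia-responsive genes differed as a list (7 of 29 called, 17 adjusted over the list alone, mean 0.69, camera adjusted p = 2.96e-35; adjusted p = 0.000687 with an estimated correlation). So did glycolysis (3 of 20, 11 adjusted over the list alone, mean 0.64, camera adjusted p = 1.22e-18; adjusted p = 0.121 with an estimated correlation). Neither call was lost without any 1 array. Tip cell genes (0 of 14, 1 adjusted over the list alone, mean 0.21, camera adjusted p = 0.00497; adjusted p = 0.0998 with an estimated correlation) lost the call without SD room air day 5 replicate 2 or SD room air day 6 replicate 1. The antioxidant list (1 of 30, 2 adjusted over the list alone, mean 0.17, camera adjusted p = 0.00771; adjusted p = 0.237 with an estimated correlation) was called too. So was the cell cycle list (0 of 34, mean −0.35, camera adjusted p = 2.81e-08; adjusted p = 0.81 with an estimated correlation). The latter was lost at −0.08 without SD room air day 5 replicate 2 and at −0.14 without SD room air day 6 replicate 1, and lay at −0.61 and −0.56 without their partners. At an unadjusted p under 0.05 there were 541 genes. The count of 16 was 2 and 7 without SD hyperoxia day 5 replicates 1 and 2, and 5 and 3 without SD hyperoxia day 6 replicates 1 and 2. It was 9 without SD room air day 5 replicate 1 and 8 without SD room air day 6 replicate 2. Egln3 and Pdk1 were the 2 of 8 named genes called in all 16 fits.

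In F344 146 genes differed between days, 39 more positive and 107 more negative on day 6. Ak4 (2.13 ± 0.21, n = 2 arrays per group, 4.37-fold, adjusted p = 0.000414), Slc16a3 (1.74, adjusted p = 0.0249) and Egln3 (1.62, adjusted p = 0.00607) were the most positive. Ankrd37 (1.55), Pfkfb3 (1.46), Tm4sf1 (1.38, adjusted p = 0.00858), P4ha1 (1.34, adjusted p = 0.0278) and the uncertain globin Hbb (1.35, adjusted p = 0.0254) came next. Most negative were Cdk4 (−1.29, adjusted p = 0.0159), Mrpl38 (−1.28, adjusted p = 0.0213), and Irf2bpl (−1.27, adjusted p = 0.0191). Prrc2a (−1.26, adjusted p = 0.0383), Tlcd3b (−1.22, adjusted p = 0.0471), Zmiz2 (−1.20, adjusted p = 0.0249), the cell cycle phosphatase Cdc25b (−1.19, adjusted p = 0.0364) and Hcfc1 (−1.19, adjusted p = 0.0254) followed. Hypoxia-responsive genes (10 of 29 called, 13 adjusted over the list alone, mean 0.61, camera adjusted p = 1.71e-14; adjusted p = 0.0156 with an estimated correlation) differed as a list. So did glycolysis genes (3 of 20, 8 adjusted over the list alone, mean 0.52, camera adjusted p = 1.39e-06; adjusted p = 0.504 with an estimated correlation). Both were called in every fit with an array left out, the glycolysis mean being 0.34 without F344 hyperoxia day 6 replicate 1. At an unadjusted p under 0.05 there were 2093 genes. The count of 146 was 9 and 18 without F344 hyperoxia day 5 replicates 1 and 2, 494 without F344 hyperoxia day 6 replicate 1 and 21 without F344 room air day 5 replicate 1. It was 2 and 4 without F344 room air day 6 replicates 1 and 2, 53 without either array of the SD hyperoxia group of day 5 and 66 without either of that of day 6. Ak4 was the 1 of 16 named genes called in all 16 fits.

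Weaker list differences between days in F344 were seen in vascular genes. These were the angiogenic list (1 of 33 called, 1 adjusted over the list alone, mean 0.14, camera adjusted p = 0.0232; adjusted p = 0.436 with an estimated correlation) and the endothelial list (0 of 29, 0 adjusted over the list alone, mean 0.15, camera adjusted p = 0.0232; adjusted p = 0.504 with an estimated correlation). Others were tip cells (0 of 14, 1 adjusted over the list alone, mean 0.22, camera adjusted p = 0.0232; adjusted p = 0.237 with an estimated correlation) and pericytes (1 of 14, 1 adjusted over the list alone, mean 0.26, camera adjusted p = 0.0232; adjusted p = 0.455 with an estimated correlation). All 4 were lost without F344 room air day 5 replicate 2, where the endothelial mean was 0.04 and the pericyte mean 0.13, and without F344 hyperoxia day 6 replicate 1. The angiogenic, endothelial and pericyte calls were also lost without F344 hyperoxia day 5 replicate 2. So were the angiogenic call without F344 room air day 6 replicate 1 and the pericyte call without F344 hyperoxia day 6 replicate 2. The endothelial mean was 0.26 without F344 room air day 5 replicate 1. The clock list was more negative on day 6 (0 of 13, 4 adjusted over the list alone, mean −0.34, camera adjusted p = 0.00137; adjusted p = 0.504 with an estimated correlation; lost without F344 room air day 5 replicate 2).

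**Figure D3:**
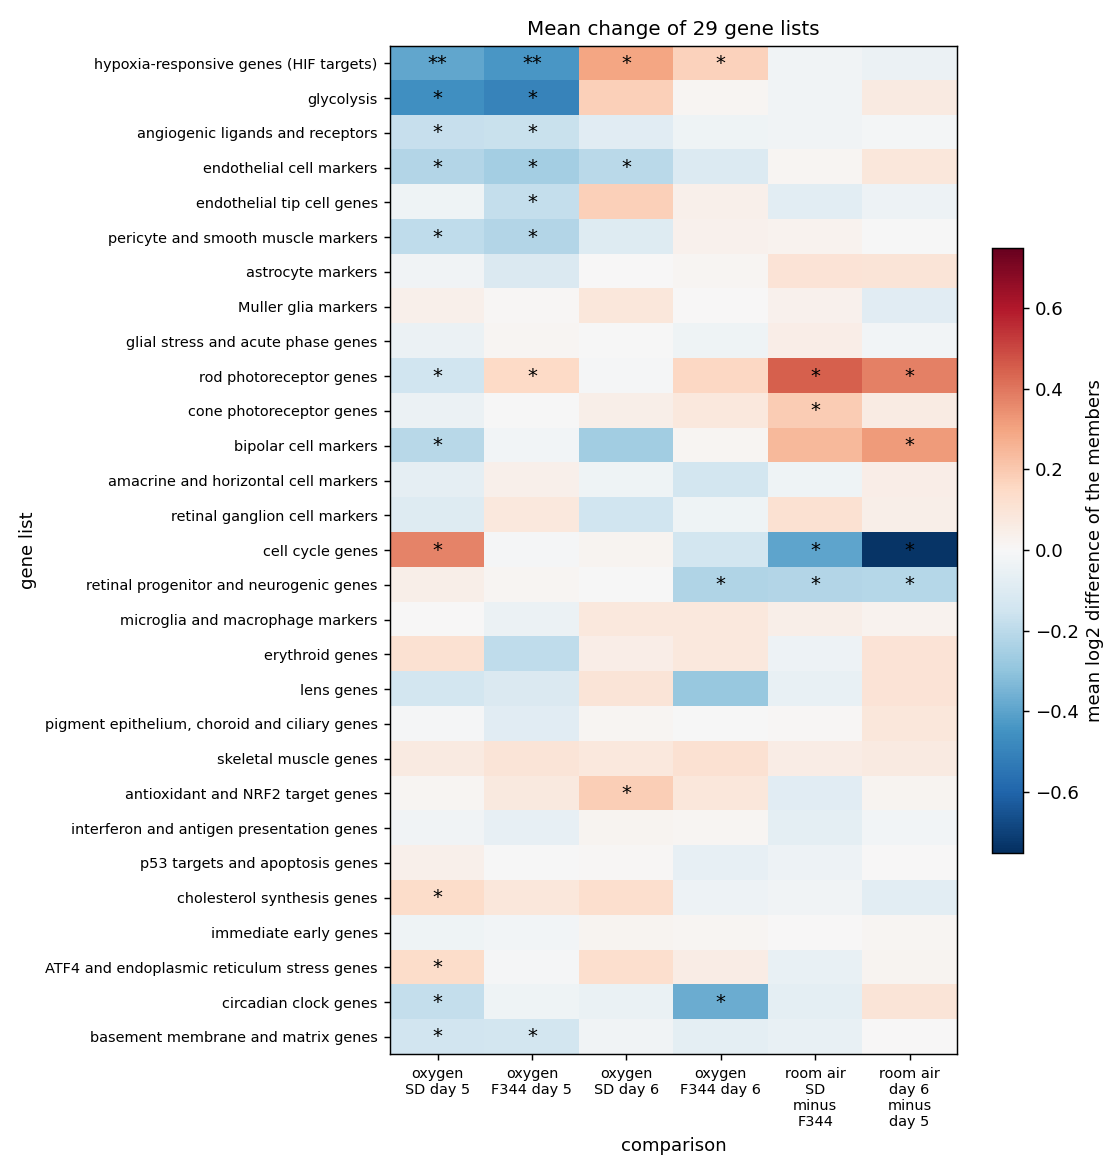
Heat map of the mean log2 difference of each of 29 gene lists (y axis) in 6 comparisons (x axis), where 1 star marks a camera adjusted p under 0.05 and a pair of stars marks lists called with an estimated correlation as well. Hypoxia-responsive genes lie at −0.39 in SD and −0.44 in F344 on day 5 and at 0.29 and 0.17 on day 6.

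Among rats in room air, the strains differed for 1340 genes, 576 higher and 764 lower in SD than in F344. Mospd1 (10778399, 1 of 2 probe sets) was at least 25.8-fold lower in SD (−4.69 ± 0.12, n = 2 arrays per group, adjusted p = 1.18e-12), at 4.19 ± 0.07 against 9.12 ± 0.4 on day 5. Ly6g6e was 6.19-fold lower (−2.63 ± 0.08, adjusted p = 5.62e-12). The antigen peptide transporter Tap2 (−1.78, adjusted p = 7.51e-09), Ly6g6d (−1.52) and the G protein subunit Gng11 (−1.45) were lower too. So were H2ac4 (−1.33, adjusted p = 0.0188), the collagen gene Col5a3 (−1.25, adjusted p = 4.32e-06) and the cell cycle kinase Cdk1 (−1.23, adjusted p = 0.00107). Pter was at least 5.93-fold higher in SD (2.57 ± 0.12, adjusted p = 1.8e-09) and the anion exchanger Slc26a7 at least 5.65-fold higher (2.50 ± 0.11, adjusted p = 1.12e-09). They were followed by Tex26 (1.63), Pth2r (1.59), Tmco3 (1.54), Pax4 (1.41) and the uncertain RT1-DOb (1.58) and RT1-Bb (1.49). Probes could not be compared with strain sequences here, so that a variant under a probe can lower a signal without a change in RNA. At an unadjusted p under 0.05 there were 3346 genes. The count of 1340 was 615 without F344 room air day 5 replicate 2, and 657 and 618 without F344 room air day 6 replicates 1 and 2. It was 713 without SD room air day 5 replicate 2 and 887 without SD room air day 6 replicate 2. H2ac4 alone of the 16 named genes lost its call, in each of those fits but that without F344 room air day 6 replicate 1.

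Cell type lists differed between strains in room air as well. Of 21 rod genes, 11 were higher in SD (12 adjusted over the list alone, mean 0.45, camera adjusted p = 4.06e-08; adjusted p = 0.595 with an estimated correlation). Of 13 cone genes, 4 were (5 adjusted over the list alone, mean 0.19, camera adjusted p = 0.00396; adjusted p = 0.217 with an estimated correlation). Of 34 cell cycle genes, 11 were lower in SD (20 lower and 1 higher adjusted over the list alone, mean −0.40, or −0.26 without SD room air day 5 replicate 2, camera adjusted p = 3.6e-11; adjusted p = 0.758 with an estimated correlation). Of 16 retinal progenitor genes, 5 were (6 lower and 1 higher adjusted over the list alone, mean −0.22, camera adjusted p = 0.0302; adjusted p = 0.758 with an estimated correlation), a call lost without F344 room air day 5 replicate 1, SD room air day 5 replicate 2 or SD room air day 6 replicate 2. The median rod gene was higher in SD by 0.48 on day 5 and 0.51 on day 6. Replicate SD arrays differed between themselves in these lists, with a mean over the cell cycle list of 7.8 and 7.26 on day 5 and 7.1 and 6.67 on day 6, against 8.07 and 7.96 and then 7.25 and 7.14 in F344.

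From day 5 to day 6 in room air, dividing-cell genes fell and photoreceptor genes rose in the mean over both strains. The mitotic gene Pbk fell by 1.32 on the log2 scale (± 0.14, n = 2 arrays per group, adjusted p = 0.000798), Nusap1 by a like amount (−1.32 ± 0.17, adjusted p = 0.00112) and the replication factor Pclaf 2.53-fold (−1.34 ± 0.21, adjusted p = 0.00305). Further falls were in Cep55 (−1.25, adjusted p = 0.00253), Ect2 (−1.19), Kif4a (−1.17), Ndc80 (−1.16, adjusted p = 0.00112) and Fbxo5 (−1.12). Rhodopsin kinase Grk1 rose (1.02 ± 0.17, adjusted p = 0.00465). So did the photoreceptor genes Gucy2f (0.87, adjusted p = 0.00761) and Guca1b (0.82, adjusted p = 0.0324) and the bipolar cell channel Trpm1 (1.33, adjusted p = 0.0155). Scgn (1.42, adjusted p = 0.0338), the GABA receptor Gabrr1 (0.95, adjusted p = 0.00515), Isl1 (0.93, adjusted p = 0.0344) and Pth2r (0.88, adjusted p = 0.00742) rose too. Of 34 cell cycle genes, 27 fell (33 adjusted over the list alone, mean −0.73, camera adjusted p = 1.35e-42; adjusted p = 0.203 with an estimated correlation). Of 16 progenitor genes, 2 fell (6 down and 1 up adjusted over the list alone, mean −0.21, camera adjusted p = 0.00041; adjusted p = 0.256 with an estimated correlation). Of 21 rod genes, 4 rose (16 adjusted over the list alone, mean 0.37, camera adjusted p = 6.71e-13; adjusted p = 0.216 with an estimated correlation). Of 12 bipolar genes, 3 rose (3 adjusted over the list alone, mean 0.32, camera adjusted p = 0.00227; adjusted p = 0.356 with an estimated correlation). In all, 185 genes rose and 245 fell, with 2180 at an unadjusted p under 0.05. The count of 430 was 136 and 676 without F344 room air day 5 replicates 1 and 2, and 185 and 112 without F344 room air day 6 replicates 1 and 2. It was 92 without SD room air day 5 replicate 1 and 144 without SD room air day 6 replicate 2. In all 16 fits, 10 of 16 named genes, among them Grk1, Gabrr1 and the 8 that fell, were called.

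**Figure D4:**
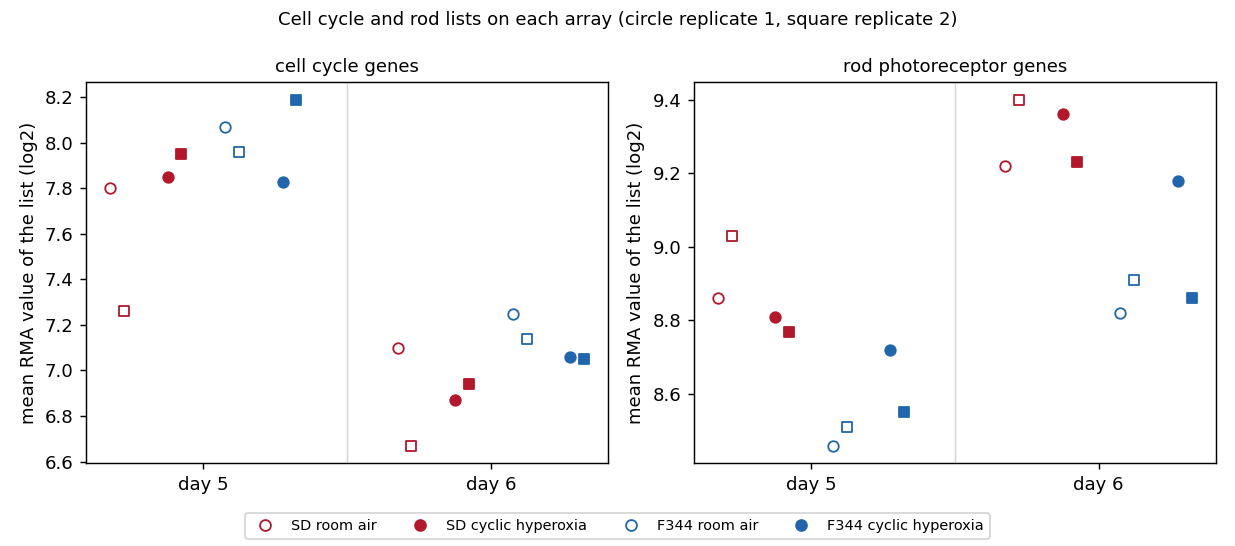
Mean RMA log2 value per array (y axis) of the cell cycle and rod lists in each group (x axis), with circles for replicate 1, squares for replicate 2, open symbols for room air and filled symbols for cyclic hyperoxia. In room air the cell cycle mean falls from between 7.26 and 8.07 on day 5 to between 6.67 and 7.25 on day 6.

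Of the 29 lists tested in 12 comparisons, 12 were called in none by camera with the preset correlation. Their smallest adjusted p values were 0.136 for astrocytes, 0.48 for Muller glia, 0.572 for glial stress and 0.13 for amacrine and horizontal cells. They were 0.0721 for ganglion cells, 0.0706 for microglia and macrophages, 0.261 for lens and 0.14 for pigment epithelium with choroid and ciliary body. They were 0.0757 for skeletal muscle, 0.24 for interferon and antigen presentation, 0.589 for p53 targets and 0.586 for immediate early genes. In all, 64 list shifts were called, of which 6 were called with an estimated correlation.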

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

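Of the tests in this part, the day 6 counts without the array that stood apart, the comparison of replicate SD pools, the covariate for array spread, the comparison of neighbouring genes with other contrasts, the test of endothelial share, the tests of gene length in F344 and of the size of the SD changes, the splits with a term for strain or day and the strain difference in hyperoxia were chosen only after the result was seen.

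A tested difference between strains singled out 8 genes on day 6, with differences of the oxygen effect, SD minus F344, of 1.33 for Slc35a4, 1.29 for Fibp, 1.21 for Plbd2, 1.09 for Rnd2, 0.98 for Pkdcc, 0.92 for Dpysl4, 0.92 for Rhob and −0.92 for Chrm2. Lists with a tested strain difference were rods (−0.30), the cell cycle (0.38) and erythroid genes (0.30) on day 5 and the clock (0.32) on day 6. All 4 calls were lost with an estimated correlation (adjusted p from 0.815 to 0.91).

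A tested difference between days, day 6 minus day 5, singled out 16 genes in SD, named among them Slc16a3 (2.41), Cox4i2 (2.13), Egln3 (2.05), Igfbp2 (1.78), Gipr (1.64), Ak4 (1.53), Pygl (1.49) and Pdk1 (1.41). In F344 it singled out 146 genes, named among them Ak4 (2.13), Slc16a3 (1.74), Egln3 (1.62), Ankrd37 (1.55), Pfkfb3 (1.46), Tm4sf1 (1.38), the uncertain Hbb (1.35), P4ha1 (1.34), Cdk4 (−1.29), Mrpl38 (−1.28), Irf2bpl (−1.27), Prrc2a (−1.26), Tlcd3b (−1.22), Zmiz2 (−1.20), Cdc25b (−1.19) and Hcfc1 (−1.19). Lists with a tested difference between days were, in SD, hypoxia-responsive genes (0.69), glycolysis (0.64), tip cells (0.21), the cell cycle (−0.35) and antioxidant genes (0.17), and in F344 hypoxia-responsive genes (0.61), glycolysis (0.52), angiogenic genes (0.14), endothelial markers (0.15), tip cells (0.22), pericytes (0.26) and the clock (−0.34). With an estimated correlation only the hypoxia-responsive lists stayed called (adjusted p = 0.000687 in SD and 0.0156 in F344). The others then lay at adjusted p between 0.0998 (tip cells) and 0.81 (cell cycle) in SD, and between 0.237 (tip cells) and 0.504 in F344.

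On day 6 many more genes were called with hyperoxia than on day 5, for which a response of the retina to the oxygen cycle stays open and untested. The F344 array that stood apart enters the SD comparison through the shared spread alone, and the 4 SD arrays of that day by themselves called 233 genes, which argues against it as the source in SD (the 994 without it decides nothing, being 994 without its partner as well). In F344 the count was 0 without that array, as it was without either room air array of day 6, but 1621 with it as the lone hyperoxia array, so that the F344 count may come from it. An axis of array quality stays open for SD, because across its 400 called genes, which are not independent replicates, the change correlated with the difference between the F344 hyperoxia replicates of day 6 (Pearson's r = 0.588, 69% of the same sign), against −0.476 to 0.338 for the replicates of 5 other groups, and the covariate for array spread decides nothing, since it raised the count to 1289 but left the median size of the called SD changes at 0.635. Over all genes the SD change fell with genomic span (Spearman −0.335). Median spans were 8.8 kb for risers, 102.3 kb for fallers and 18 kb for all genes. Removing each array's trend with span left 91.1% of the median SD change (0.635 before, 0.579 after, median SE 0.137 and 0.133). These genes were chosen for large changes beforehand, so this argues only against the average trend as the whole source of their size. For the number of SD genes, length cannot be told apart from a change with oxygen. The count fell from 400 to 248, 222 of them called before, and the p needed for a call from 0.00139 to 0.000865. In F344 141 of the 162 genes called before among those with a span were still called. This argues against that trend as the whole source there.

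In room air, rod genes were higher and cell cycle genes lower in SD than in F344. With each array's interquartile range as a covariate the means were 0.473 for rods and −0.334 for the cell cycle (camera adjusted p = 4.69e-07 for each). This decides nothing about array quality, because in room air the interquartile range differed little between strains (−0.0579, SD minus F344). The covariate left the median size of the called strain changes at 0.441, against 0.431 before. Array quality therefore stays open. Without the covariate both lists lost their call with an estimated correlation. A difference in developmental stage is a candidate explanation, since across genes called between days the strain difference correlated with the day difference (r = 0.317, against −0.029 across all genes). Pools that differ in stage are another, since over the rod and cell cycle genes the difference between the SD room air replicates of day 5 correlated with the F344 day difference (r = 0.866, against 0.423 across all genes), the median cell cycle gene being lower in replicate 2 (−0.457). Whether the strains themselves or the few pools drawn from them differ in stage stays open.

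Endothelial markers were lower with hyperoxia on day 5 in both strains, a call lost with an estimated correlation (adjusted p = 0.21 in SD, 0.0831 in F344 and 0.0677 over both). A lower share of endothelial cells would lower all of their transcripts alike, but it cannot be told apart from lower expression per cell here. The median change of the markers with a room air mean of at least 7 was 0.088, against −0.754 for the called members, yet 1 marker, Podxl, was the lone one to reach that level, which makes the test void. A response of endothelial cells to oxygen stays open and untested.

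The strain difference in room air held 164 pairs of neighbouring genes called together, against a highest value of 163 in 10000 shufflings of gene order (permutation p = 1e-04, the smallest they can give). Variants linked to position are not singled out by this, because neighbouring pairs were also in excess for oxygen on day 6 (1.38 times the shuffled mean, permutation p = 0.0013) and at a like ratio for the day difference (1.47, permutation p = 0.0634), as against 1.31 for strain. Grouping by chance was tried with fits of 8 arrays in 2 groups without a term for strain or day. Over both strains on day 5 the real split called 16 genes and the highest other 299, so that 2 of 35 splits gave as many, and for strain in room air the real split called 267 and the highest other 423, 2 of 35 being as large. These counts of splits alone do not exclude chance, but on day 5 the highest other split is that by strain, a structure of the samples, and all the rest called 0. Other values argue against chance for both results. The strains, which share no array, had 8 falls in common on day 5 against 0.0113 by chance, and 541 of the 1340 genes called between strains in room air were called in the same direction in the hyperoxia arrays, against 58.7 by chance. With a term for strain or day and splits balanced over it, the real split called 27 genes and the highest other 1 for day 5, 217 and 1 for day 6, 497 and 0 for strain, and 70 and 1197 for day, where 18 splits are too few for a share under 0.05. Without such a term the real split called 0 genes and the highest other 553 on day 6, and 0 and 423 for day in room air, so that 35 of 35 splits being as large was fixed beforehand and says nothing about chance. The highest split in room air parts the F344 arrays by day and sets both first SD replicates with day 5 and both second ones with day 6, which points to a structure of the samples in which the SD pools differ.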

How the results depend on the processing

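The covariate for array spread and the replicate block across days were chosen after seeing the data, and the other alternatives were planned. Counts kept within 1.5 times their value in 251 recalculations and moved in 136. Single genes and lists kept direction and side of the threshold in 8588, were weaker in 1105, stronger in 36 and reversed in 0. Median centring moved none of the 12 counts, nor those of named genes called (177) and list shifts called (64), and the mean of a gene's probe sets, not run on lists, moved none of the others. The cause was not tested for the counts that moved, except that the added demand of a fold of 1.5 can by construction only lower counts. Signal over background limits dim genes, and omitting the genes with the lowest means moved the count for the strain difference on day 6 alone. Replicate numbers did not pair arrays of a day across groups (Pearson's r of replicate differences across genes from −0.287 to 0.395, median −0.0565, 12 pairs of groups). Across days the values lay between −0.286 and 0.519 (median −0.0075, 16 pairs). The days of 1 strain and treatment gave 0.519 (SD room air), 0.248 (F344 room air), 0.217 (SD hyperoxia) and −0.034 (F344 hyperoxia). A pairing of replicate numbers across days is thus not excluded, most of all in SD room air. A replicate block across those days gave 18 genes for the day difference in SD, against 16 without it. It gave 513 in F344, against 146, and 824 for day in room air, against 430.

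Without moderation the counts were 1 (SD day 5), 51 (SD day 6), 0 (F344 day 5), 7 (F344 day 6), 10 (both strains day 5), 205 (both day 6), 1 and 27 (day difference of the oxygen effect in SD and F344), 615 (strain in room air), 0 (day in room air) and 45 (named genes). With the compared groups alone they were 16 and 233 (SD day 5 and 6), 4 and 0 (F344 day 5 and 6), 396 (both day 6), 0 (strain difference day 6), 1 (day difference F344), 214 (day in room air) and 115 (named genes). With array weights they were 28 and 800 (SD), 0 (F344 day 6), 58 and 494 (both), 0 (strain difference day 6) and 18 (day difference F344). With a fold of at least 1.5 they were 257 (SD day 6), 118 (both day 6), 257 (strain in room air) and 139 (day in room air). Trend and robust fitting gave 74 (F344 day 6), 3 (strain difference day 6) and 61 (day difference F344), and every probe set on its own gave 111, 14 and 68. Without the genes with the lowest means the strain difference on day 6 counted 5. Quantile normalization gave 4 for it (3 higher, 1 lower, against 7 and 1), 76 for the day difference in F344 (32 and 44, against 39 and 107), and shifted F344 day 6 to 48 and 67, against 49 and 121. A replicate block gave 68 (F344 day 6), 2 (strain difference day 6), 58 (day difference F344) and 65 (day in room air). Its other counts kept within 1.5 times of the main ones. The covariate for array spread gave 1289 (SD day 6), 31 (F344 day 5), 327 (strain difference day 6), 476 (day difference F344) and 2309 (strain in room air). List shifts called were 6 with an estimated correlation and 24 by fry, against 57 by camera on ranks.

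Leaving out each array in turn gave 0 to 15 genes for SD day 5, 0 to 994 for SD day 6, 4 to 19 for F344 day 5, 0 to 1621 for F344 day 6, 14 to 54 and 53 to 2829 for both strains on day 5 and 6, 0 to 2 and 0 to 181 for the strain difference on day 5 and 6, 2 to 20 and 2 to 494 for the day difference in SD and F344, 615 to 1844 for strain and 92 to 676 for day in room air, 106 to 184 named genes and 54 to 75 list shifts, the arm left with 1 array being assumed to vary like the other groups.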

Other observations

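All tests in this part were chosen only after the results of the comparisons were seen. Gene families defined by symbol and tested as lists showed a rise in protein and energy machinery over both strains on day 6. Of 39 proteasome genes 18 rose (median log2 change 0.32, camera adjusted p = 1e-15; adjusted p = 0.0155 with an estimated correlation), and of 67 mitochondrial ribosome genes 27 rose (median 0.29, camera adjusted p = 9.76e-18; adjusted p = 0.0155 with an estimated correlation). Of 76 cytosolic ribosome genes 37 rose and 1 fell (median 0.36, camera adjusted p = 1.18e-21; adjusted p = 0.0712 with an estimated correlation), and of 37 respiratory complex I genes 17 rose (median 0.32, camera adjusted p = 1.88e-13; adjusted p = 0.0643 with an estimated correlation). Complex IV (6 of 16, median 0.28, camera adjusted p = 4.32e-06) and ATP synthase (6 of 16, median 0.25, camera adjusted p = 7.34e-06) showed the same direction (adjusted p = 0.0829 with an estimated correlation for each). With an array left out the proteasome median lay between 0.30 and 0.34 and the mitochondrial ribosome median between 0.25 and 0.34. The ranges were 0.31 to 0.37 for complex I, 0.30 to 0.43 for the cytosolic ribosome, 0.25 to 0.33 for complex IV and 0.17 to 0.37 for ATP synthase (0.17 and 0.37 without F344 room air day 6 replicates 1 and 2), and none of these 6 families changed direction under quantile normalization or median centring. These are short, abundant transcripts, and the weighing of array quality and gene length for day 6 applies to them. All 6 families were also called higher on day 5 over both strains by camera, with 0 genes called in any of them and none of the 6 called with an estimated correlation. The medians were 0.18 for the proteasome (camera adjusted p = 1.24e-09), 0.17 for complex I (2.33e-05) and 0.13 for the cytosolic ribosome (2.25e-06). They were 0.09 for the mitochondrial ribosome (0.00123), 0.20 for ATP synthase (0.00038) and 0.12 for complex IV (0.00659). With an estimated correlation the adjusted p lay between 0.0804 and 0.271. Without hyperoxia, in room air, the cytosolic ribosome was lower in SD than in F344 (24 of 76 called, median −0.23, camera adjusted p = 2.29e-09). The proteasome and mitochondrial ribosome (camera adjusted p = 0.00197 for each) and ATP synthase (0.0497) were lower too. All were lost with an estimated correlation, and complex I and IV were not called. Without F344 hyperoxia day 5 replicate 2 the medians fell to 0.06 for complex I, 0.05 for the cytosolic ribosome, 0.10 for ATP synthase and 0.04 for complex IV, and without its partner that of the cytosolic ribosome was 0.20. On day 6 1104 olfactory receptor genes were called higher too at a median of 0.03, −0.02 with quantile normalization (camera adjusted p = 0.0181; adjusted p = 0.52 with an estimated correlation), and 83 potassium channel genes lay at −0.04 (camera adjusted p = 0.11; adjusted p = 0.333 with an estimated correlation). Neither is steady. The olfactory receptor median was 0.00 without F344 hyperoxia day 6 replicate 2, the array that stood apart, and 0.06 without its partner. With an array left out the potassium channel median lay between −0.05 and −0.02.

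The oxygen effects of the 2 days were also compared across genes, which are not independent replicates, for pairs of effects with no array in common. Pearson's r was 0.213 between strains on day 5, 0.328 between strains on day 6, 0.564 between days in SD and −0.06 between days in F344. In SD, 375 of the 400 genes called on day 6 had the same sign on day 5, whereas Egln3 and Pdk1 were called in opposite directions on the 2 days. In F344, 50 of the 170 genes called on day 6 had the same sign on day 5.

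Over the 55 rod and cell cycle genes, the oxygen effect in SD on day 5 correlated with the day difference of F344 in room air at r = −0.691, and that in F344 on day 5 with the day difference of SD at 0.317. On day 6 the values were 0.141 for SD and 0.577 for F344. Differences between replicates, 2 minus 1, were set against the day difference of the other strain over the same genes. Against that of F344 the values were 0.866 and 0.815 for SD room air on day 5 and 6 and −0.452 and −0.525 for SD hyperoxia. Against that of SD they were 0.252 and 0.623 for F344 room air and −0.777 and −0.624 for F344 hyperoxia.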
